A study of Danio rerio with 16 samples.

How the data were processed

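RNA from pools of zebrafish embryos of the TL strain was measured on 16 single-colour (Cy3) Agilent oligonucleotide arrays, with 4 arrays per slide. Per the labels' protocols, embryos received about 100 pg of in vitro transcribed mRNA at the 1-2 cell stage, in a volume of about 2.1 nL at 50 ng/µL. The mRNA encoded either a dominant-negative form of the metal-responsive transcription factor MTF-1 fused to eGFP (dnMTF-1) or eGFP alone as the control. The injected embryos of each treatment were divided into 4 pools of 30, held in 25 mL of medium at 28.5 °C with 14 h of light and 10 h of dark. Embryos positive for eGFP were frozen at 28 or 36 hours post-fertilization (hpf). Each pool gave 1 RNA sample, and 750 ng of Cy3-labelled material was hybridized to 1 array.

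Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.1.1.1, with spatial and multiplicative background detrending switched on and no normalization between arrays. The processed intensity per spot was background-subtracted and on a linear scale. The deposited value table also held intensity on a linear scale, for 21315 probes. Per the labels, the authors normalized these values with a nonlinear scaling through rank-invariant probes and removed saturated probes and probes not above background. They then log-transformed and median-centred the data for a 2-factor test and for rank products within each time. The deposited array medians lay between 758.4 and 808.4 and the lowest rank correlation with the processed intensity of the same array was 0.9991, so the table holds values from before the log and centring steps. Which software made the table, and which filter chose its probes, is not stated.

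Each array had 43786 non-control spots for 21893 probes with 2 spots per probe. Between 38 and 163 spots per array carried a non-uniformity or population outlier mark and were left out. No spot was saturated, so a filter on saturation removed nothing. The share of probes well above background was 87.81% to 93.41% per array, and the number of arrays, 4 per group, limits the precision. The values were taken as log2 of the processed intensity, and replicate spots were averaged. Each array was fitted to the median of all arrays with a loess curve (span 0.3) through its rank-invariant probes, whose ranks differed by less than a share of 0.003 for dim to 0.007 for bright probes, which left 3305 to 5802 such probes per array. Probes well above background on all 4 arrays of at least 1 group were tested, 19953 in all.

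Differences were tested with limma 3.58.1 in R 4.3.3 on a group-means model over all 16 arrays with an intensity trend in the variance, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. All tests were two-sided. The comparisons were dnMTF-1 against eGFP at 28 hpf, at 36 hpf and over both times, the treatment by time interaction, and 36 against 28 hpf within each treatment. Errors given with log2 fold changes are standard errors (SE) from this model. A difference against a group in which no array was well above background is given as a lower limit, computed against the lowest well-above-background value of each array.

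Gene names came from the array files and, where the accession, symbol or synonym of a probe matched, from the RefSeq gene table of assembly GRCz12tu, which was used for names only. By accession 7324 probes matched, by symbol 617 and by synonym 2359, and 11593 kept the name in the file. Names that are gene symbols covered 10487 probes and 7241 distinct symbols. Positions are those of the array files, whose annotation names build danRer2, and they were not checked because no genome of that build was at hand. For tests of gene lists each gene was represented by its brightest probe, which gave 16537 genes, 6966 of them with a symbol.

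The 30 gene lists (tissues, pathways and metal biology) were fixed before the data were examined, as were the comparisons, the rule for named genes and nearly all alternatives. The lists were tested at both times, 60 tests adjusted together, with limma's camera at its preset correlation between genes of 0.01. The same tests were run with an estimated correlation, and with fry, which tests whether a list's genes move one way without comparing them with other genes. One gene and 1 list are not reported here, though the counts include them. Counts of list members past the threshold are given over all probes tested and, for the lists described in the results, also adjusted over the list alone.

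Named genes were the 10 highest rises and the 10 deepest falls by log2 fold change for each time, among probes past the threshold whose 4 values per group did not overlap, with the brighter group above background on every array. The 5 most extreme each way for the interaction and 10 each way for time in eGFP embryos followed the same rule, without the overlap condition for the interaction. To these were added mtf1, the 3 metallothionein probes, and the members of each list with the smallest p. The rule allowed up to 4 such members and 2 per list were taken. That number was set after the data had been seen. Where the highest-ranked members of a list did not pass the test at the time described, their values are given as measured.

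The replicate numbers of the 4 groups follow the array position on the slide. Of the 24 pairs of arrays with the same number in different groups, 9 correlated above 0.1 after removal of group means (median 0.064, range -0.414 to 0.328). Only 5 of 16 arrays correlated best with an array of their own number. The numbers were therefore not used to pair samples. A slide held the 4 arrays of 1 group, so no fit with slide as a term could be had.

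On simulated data for the 28 hpf comparison, with each probe's spread as in the fit over 19952 probes, the procedure recovered 52% of changed probes at a log2 difference of 0.25, 70% at 0.5, 96% at 1 and 100% at 2. It made 5 false calls among 164, and 0 calls in an unchanged 36 hpf comparison. The simulation changed 200 probes, held no time effect and distorted each array independently. How normalization and false calls fare where many probes change, or where slides follow groups, was therefore not shown. With 30 lists over 16000 genes, camera called the 1 list that had been shifted by 0.3 and 0 of the others. These genes were drawn independently of each other. The simulation therefore could not show how camera's preset correlation fares where list members vary together, such as the liver list at 28 hpf (estimated correlation 0.45). The rank product with 100 permutations made 160 calls for 200 changed probes where all probes varied equally and 0 in the unchanged comparison. Where probes varied as in the data it made 246 calls, with 109 in the unchanged comparison.

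The alternatives were the 75th percentile, quantile and absent normalization, normexp background correction with an offset of 50, and the authors' deposited values. Others were the filters on dim probes and marked spots, the threshold, array weights and a fit without the intensity trend. Further ones were a fit of the compared groups alone, the replicate number as a block and the mean of a gene name's probes. Tests modelled on the authors' own were also run, and each array was left out in turn. A slope of treatment effects without the lens and retina lists was added after the data had been seen. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.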

Results

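Gene expression was measured in pools of 30 zebrafish embryos after injection of mRNA for dnMTF-1, a form of the zinc-sensing transcription factor MTF-1 that blocks the embryo's own MTF-1, or of eGFP mRNA as the control. The 16 arrays formed 4 groups of 4 pools, eGFP and dnMTF-1 at 28 hpf and at 36 hpf. Between 87.81% and 93.41% of probes per array were well above background, and the median processed intensity ranged from 551.3 (dnMTF-1 at 36 hpf, replicate 4) to 866.7 (eGFP at 36 hpf, replicate 1). The 4 arrays of a group lay on 1 slide, so slide and group cannot be told apart. The pools of a treatment were divided after injection, so p-values measure the spread between these pools only. Each value below is a mean over n = 4 arrays per group, and fold changes are dnMTF-1 relative to eGFP with their SE.

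Time after fertilization separated the arrays most. The first principal component held 56.2% of the variance and separated 28 from 36 hpf, and the second held 13.1% and placed each dnMTF-1 group above the eGFP group of its time. At 36 hpf, dnMTF-1 replicate 4 lay at 30.3 on the second component and the other 3 arrays of its group between 9.3 and 15.4. Within groups the SD of the log2 difference between a pair of arrays was 0.172 to 0.323, and between groups it was 0.284 to 0.609.

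**Figure D1:**
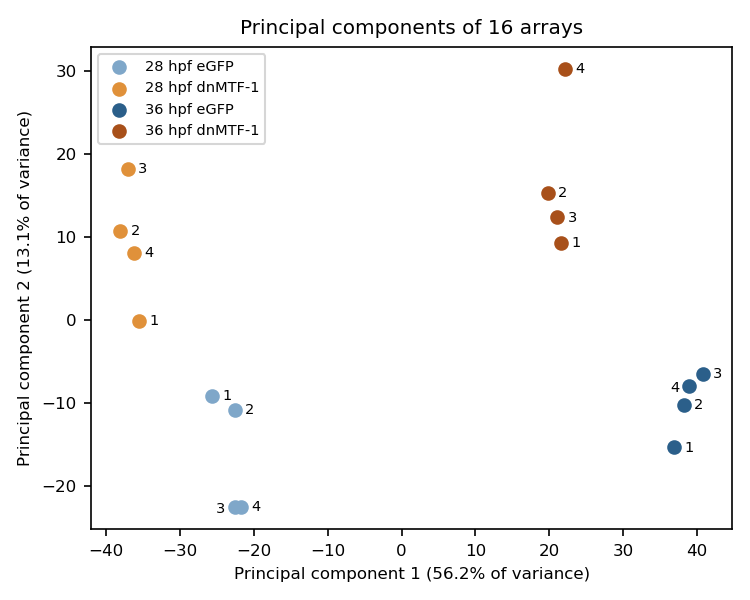
The 16 arrays by their scores on the first (56.2% of variance) and second (13.1%) principal component of log2 signal, 4 points per group. Arrays at 28 hpf lie on the left and at 36 hpf on the right, and dnMTF-1 replicate 4 at 36 hpf is the highest point at 30.3.

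The first question was whether MTF-1 and its classical target, metallothionein, changed. One metallothionein probe fell strongly in dnMTF-1 embryos and the other 2 did not. Probe A_15_P105247 (mt2, build danRer2, chromosome 14, 44565337 to 44565396) was 2.23-fold lower at 28 hpf (log2 fold change -1.16 ± 0.13, adjusted p = 1.9e-05) and 6.96-fold lower at 36 hpf (-2.8 ± 0.13, adjusted p = 2.4e-09). Its mean log2 signal rose from 10.88 to 12.19 between 28 and 36 hpf in eGFP embryos, and was 9.72 and 9.39 in dnMTF-1 embryos. The fall at 36 hpf was the larger (difference between times -1.64, adjusted p = 9.3e-05). Probe A_15_P113136 (also mt2, chromosome 21, 28058984 to 28059043), the brightest of the 3, stood at 0.11 ± 0.05 (adjusted p = 0.1) at 28 hpf and was 0.15 ± 0.05 higher at 36 hpf (adjusted p = 0.027). That call ended when 36 hpf eGFP replicate 1 (adjusted p = 0.079), 2 (0.053) or 3 (0.051) or dnMTF-1 replicate 1 (0.08) or 4 (0.071) was left out, and with the authors' deposited values (0.069), array weights (0.07) or the compared groups alone (0.074). Probe A_15_P115043 (named mt in the files) stood at 0.05 ± 0.06 (adjusted p = 0.6) and was 0.23 ± 0.06 higher at 36 hpf (adjusted p = 0.0096, and 0.11 with normexp background correction). The mtf1 probe (chromosome 3, 18086729 to 18086788) stood at -0.14 ± 0.07 (adjusted p = 0.13) and -0.15 ± 0.07 (adjusted p = 0.088), the latter past the threshold at 0.029 with array weights and at 0.018 without 36 hpf dnMTF-1 replicate 1. Whether that probe also reads the injected mRNA is not given.

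MTF-1 targets and metal-handling genes went both ways as a group. Of 20 measured genes on the list of MTF-1 and metal-response genes, 4 rose and 3 fell at 28 hpf. At 36 hpf 7 rose and 3 fell, and the counts were the same adjusted over the list alone. Each gene name enters a list by its brightest probe, which for mt2 is A_15_P113136. The metallothionein probe that fell, A_15_P105247, is therefore in neither these counts nor the test of this list. The zinc exporter slc30a1a, a well-known MTF-1 target, was higher in dnMTF-1 embryos at 28 hpf (0.48 ± 0.04, adjusted p = 6.6e-07) and at 36 hpf (0.38 ± 0.04, adjusted p = 5.9e-06). The list did not pass the test at 28 hpf (median -0.01, mean 0, test direction up, adjusted p = 0.87) or at 36 hpf (median 0.08, mean -0.08, test direction up and fry's down, adjusted p = 0.59). Of 9 zinc transporter genes 3 rose and 1 fell at 28 hpf and 2 rose and 1 fell at 36 hpf (1 rose and 1 fell adjusted over the list alone). The importer slc39a14 was lower at 36 hpf (-0.33 ± 0.06, adjusted p = 0.00092, but -0.18 and 0.05 after 75th percentile scaling) and stood at -0.04 ± 0.06 at 28 hpf (difference between times -0.29 ± 0.09, adjusted p = 0.039). That list did not pass the test either (medians 0.07 and -0.01, adjusted p = 0.58 and 1), though it did with fry at 28 hpf (upward, 0.0054).

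At 28 hpf the question was what dnMTF-1 changed early. Genes of the lens were the clearest falls. The lens galectin gene grifin (build danRer2, chromosome 3, 33084048 to 33084107) was 4.01-fold lower (log2 fold change -2 ± 0.12, adjusted p = 2e-08), and the alpha crystallin cryaa (chromosome 1, 33769214 to 33769273) 2.73-fold lower (-1.45 ± 0.22, adjusted p = 0.00018). The gamma crystallins crygm2d18 and crygm2c fell by 1.67 ± 0.07 and 1.63 ± 0.09, the lens water channel gene zf_aqp0a by 1.6 ± 0.07 and the lens filament gene bfsp2 by 1.25 ± 0.06. The cartilage matrix gene matn3a (zgc:101120 in the files, chromosome 20, 55184493 to 55184552) was not above background on any of the 4 dnMTF-1 arrays and was at least 1.96-fold lower (adjusted p = 2.5e-06). The retinal ganglion cell factor atoh7 was 2.66-fold lower (-1.41 ± 0.11, adjusted p = 2.8e-07). Also lower were cox6b1, a subunit gene of cytochrome c oxidase (-1.49 ± 0.13), and the aldehyde dehydrogenase gene aldh8a1 (-1.3 ± 0.19).

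The highest rise at 28 hpf was fosab (fos in the files, chromosome 20, 56830779 to 56830838), a subunit of the AP-1 transcription factor, at 5.33-fold (2.41 ± 0.16, adjusted p = 7.7e-08). The Wnt agonist rspo1 was 4.09-fold higher (2.03 ± 0.24, adjusted p = 1.8e-05) and the slow muscle troponin gene tnnt1 3.42-fold higher (1.77 ± 0.17, adjusted p = 3.7e-06). The pancreatic amylase genes amy2al1 and amy2a rose by 1.7 ± 0.13 and 1.36 ± 0.12, and socs3a, a brake on cytokine signalling, by 1.43 ± 0.2. The connexin gene gjb1a (1.4 ± 0.13), the proteasome subunit gene psmb12 (1.29 ± 0.07), pyroxd1 (1.27 ± 0.17) and the urate oxidase gene uox (1.24 ± 0.07) were also higher. Other probes of zf_aqp0a, cox6b1, cryaa, aldh8a1, bfsp2, fosab and amy2a went the same way, as did 4 of 5 for uox, while the second gjb1a probe did not pass the threshold.

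By group, lens genes fell the most. The list p-values are camera's at its preset correlation unless stated otherwise. Over both times 16 of 60 list tests passed that way and 0 passed with an estimated correlation. Other splits of the arrays gave a median of 9 passing lists. Of 22 measured lens genes, 14 fell and 2 rose at 28 hpf (14 and 2 adjusted over the list alone), with a median log2 fold change of -0.74 (camera adjusted p = 1.2e-08, adjusted p = 0.14 with an estimated correlation), and of -0.35 with no filter on dim probes. Beside bfsp2, the beta crystallin cryba2a was lower (-0.99 ± 0.05, adjusted p = 1.1e-08). The initiator caspase gene casp8 was 2.31-fold higher (1.21 ± 0.08, adjusted p = 7.7e-08).

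Genes of the Notch and Hedgehog pathways, retina, neurons and skeletal muscle passed the test downward as groups at 28 hpf. Those of neural progenitors and glia did not pass (adjusted p = 0.3). In the Notch pathway list 16 of 28 genes fell and 3 rose (18 and 3 adjusted over the list alone; median -0.25, adjusted p = 9.6e-07, 0.46 with an estimated correlation), among them the proneural factors ascl1b (-0.77 ± 0.06, adjusted p = 4.9e-07) and ascl1a (-0.71 ± 0.06, adjusted p = 9.7e-07). Of 41 retina and photoreceptor genes 17 fell and 3 rose (18 and 3 over the list alone; median -0.16, adjusted p = 0.0012, 0.46 with an estimated correlation). Of 27 genes of neurons 8 fell and 0 rose, over the list alone too (median -0.13, adjusted p = 0.0073, 0.88 with an estimated correlation), zc4h2 among them (-0.15 ± 0.04, adjusted p = 0.0086, and 0.81 with normexp background correction). Hedgehog pathway genes fell in 8 of 24 cases and rose in 2 (10 and 2 over the list alone; median -0.11, adjusted p = 0.023, 0.48 with an estimated correlation), with the midbrain factor en2a at -0.49 ± 0.06 and the oligodendrocyte and motor neuron factor olig2 at -0.31 ± 0.06. Of 36 skeletal muscle genes 18 fell and 2 rose (21 and 2 over the list alone; median -0.2, adjusted p = 1.3e-05, 0.46 with an estimated correlation), including the parvalbumins pvalb1 (-0.58 ± 0.04) and pvalb4 (-0.56 ± 0.04, its other probe not past the threshold). The call for the Hedgehog list ended without 28 hpf eGFP replicate 1 (adjusted p = 0.056).

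Blood, matrix, stress and liver groups passed the test at 28 hpf too. Of 22 genes of red blood cells and heme synthesis 10 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.22, adjusted p = 0.00023, 0.46 with an estimated correlation), while the heme synthesis genes hmbsa (-0.14 ± 0.05, adjusted p = 0.054) and urod (0.05 ± 0.08, adjusted p = 0.7) did not pass. For hmbsa the adjusted p was 0.025 with 75th percentile scaling, 0.041 with quantile normalization, 0.031 with normexp, 0.038 with the deposited values, 0.046 with array weights and 0.02 without 28 hpf eGFP replicate 2, and up to 0.85 with no normalization. Of 26 extracellular matrix genes 11 fell and 2 rose, over the list alone too (median -0.12, adjusted p = 0.0076, 0.31 with an estimated correlation), with the type I collagen gene col1a2 at -0.57 ± 0.06. Of 21 genes of the heat shock and unfolded protein response 9 rose and 1 fell, over the list alone too (median 0.06, adjusted p = 0.037, 0.5 with an estimated correlation). The chaperone gene hsp70 rose by 0.82 ± 0.09 (adjusted p = 1.1e-05) and the endoplasmic reticulum chaperone partner sdf2l1 by 0.27 ± 0.03. That list's call ended with 75th percentile scaling (median 0.01, adjusted p = 0.77) and without 28 hpf dnMTF-1 replicate 3 (0.05). Of 31 genes of the liver and yolk syncytial layer 4 fell and 0 rose (0 and 0 over the list alone; median -0.22, adjusted p = 0.029, 0.88 with an estimated correlation), with prox1a at -0.16 ± 0.05 (adjusted p = 0.03, and 0.051 to 0.092 without any 1 of 6 arrays, eGFP replicates 1, 3 and 4 and dnMTF-1 replicates 1, 2 and 4) and the plasma protein gene hp at 0.23 ± 0.09 (adjusted p = 0.05). For hp the adjusted p was 0.013 with 75th percentile scaling, 0.033 with no normalization, 0.04 with the deposited values, 0.031 for probes above background on all arrays, 0.019 without the intensity trend, 0.046 with array weights and 0.049 as the mean of its probes. The liver list's call ended with fry (0.27), with the deposited values (0.051) and without 28 hpf eGFP replicate 3 (0.18) or 4 (0.064) or dnMTF-1 replicate 3 (0.32).

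Across all genes, 5710 of 19953 probes passed the limma test at 28 hpf, 3016 higher and 2694 lower, with 2638 gene symbols. The median change among them was 1.21-fold, and 111 probes differed at least 2-fold (46 higher, 65 lower). Without normalization between arrays 2230 probes passed, 1940 higher and 290 lower (87% higher against 52.8%), and en2a (-0.39, adjusted p = 0.065), olig2 (-0.21, 0.28), zc4h2 (-0.1, 0.57), sdf2l1 (0.37, 0.08) and prox1a (-0.05, 0.85) no longer did.

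At 36 hpf the same question gave deep falls in the photoreceptor factor genes crx and six7, beside the metallothionein probe above. The photoreceptor transcription factor gene crx (build danRer2, chromosome 5, 39245505 to 39245563) was 8.13-fold lower in dnMTF-1 embryos (log2 fold change -3.02 ± 0.1, adjusted p = 4.2e-11) and stood at 0.03 ± 0.1 at 28 hpf. The cone photoreceptor factor gene six7 was 5.12-fold lower (-2.36 ± 0.1, adjusted p = 5.8e-10) and ndrg1b (chromosome 16, 31197300 to 31197359), an NDRG family gene on the MTF-1 list, 5.09-fold lower (-2.35 ± 0.08, adjusted p = 4.2e-11). The lactase-like gene lctla (chromosome 7, 27059404 to 27059463) was 3.99-fold lower (-2 ± 0.09, adjusted p = 1e-09). These 3 stood at 0.04, 0.12 and -0.01 at 28 hpf. Lens genes were lower again: bfsp2 (-1.83 ± 0.06, 3.55-fold), crygm3 (-1.8 ± 0.11) and cryaa (-1.76 ± 0.22). The lens gene crygm2d15 was lower too (-1.75 ± 0.16) but had not been at 28 hpf (difference between times -1.81, interaction adjusted p = 0.00015). The AMP deaminase gene ampd1 (zgc:77905 in the files) fell by 1.68 ± 0.11, with its other probe lower too. The neuronal calcium sensor gene hpcal1 was not above background on any dnMTF-1 array and was at least 1.85-fold lower (adjusted p = 0.0016).

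The highest rises at 36 hpf were tnnt1 (2.72-fold, 1.45 ± 0.17, adjusted p = 2e-05) and fosab (2.28-fold, 1.19 ± 0.16, adjusted p = 5.7e-05). Next came the actin regulator gene abi1a (1.15 ± 0.17), the cathepsin gene ctsll (1.14 ± 0.31, adjusted p = 0.0096, and 0.068 with no normalization between arrays), arhgap4a (1.12 ± 0.13) and arl3l2 (1.12 ± 0.22). The genes socs3a (1.11 ± 0.2), npdc1a (1.08 ± 0.13), amy2al1 (1.08 ± 0.13) and amy2a (1.05 ± 0.12) completed the 10. At 28 hpf abi1a stood at 0.96, ctsll at 0.58, arhgap4a at 0.49, arl3l2 at 0.22 and npdc1a at -0.43.

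**Figure D2:**
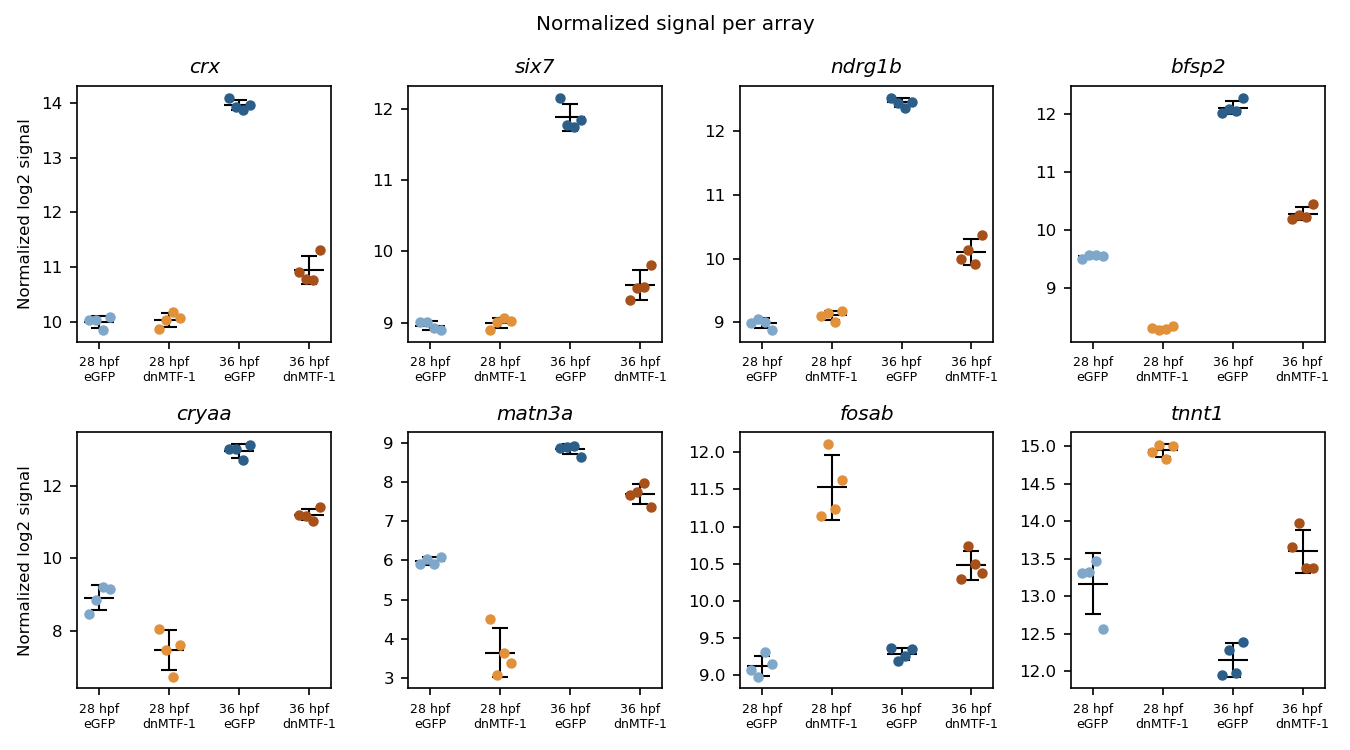
Log2 signal of 8 genes on each array in the 4 groups, with the mean and SD of each group's 4 arrays. The retinal genes crx and six7 rose between 28 and 36 hpf in eGFP embryos and far less in dnMTF-1 embryos, while fosab and tnnt1 were higher in dnMTF-1 embryos at both times.

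Lens, neuron and retina genes passed the test downward as groups at 36 hpf. Of 22 lens genes 17 fell and 0 rose, over the list alone too (median -0.6, adjusted p = 1e-11, 0.09 with an estimated correlation), with cryba2a at -0.78 ± 0.05. Of 27 genes of neurons 20 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.27, adjusted p = 3.5e-08, 0.46 with an estimated correlation). The motor neuron and retinal factor isl1a, which the retina and pancreas lists also hold, fell by 0.74 ± 0.05 (adjusted p = 2.5e-08) and zc4h2 by 0.41 ± 0.04. Of 41 retina and photoreceptor genes 16 fell and 6 rose (17 and 8 over the list alone; median -0.08, mean -0.33, adjusted p = 0.0012, 0.46 with an estimated correlation). After 75th percentile scaling the retina list's median was 0.03 with the test still downward (adjusted p = 0.0003). In the Notch pathway 13 of 28 genes fell and 2 rose (14 and 3 over the list alone; median -0.13, adjusted p = 0.0037, 0.74 with an estimated correlation), with ascl1b at -0.31 ± 0.06 and ascl1a at -0.35 ± 0.06.

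Circadian clock genes were the group that rose at 36 hpf. Of 23 measured, 10 rose and 0 fell, over the list alone too (median 0.19, adjusted p = 0.02, 0.37 with an estimated correlation). With time in eGFP embryos 16 of these 23 genes fell and 2 rose (median -0.44). Of the 27 neuron genes, lower as a group at 36 hpf, 26 rose with time (median 0.71). Both effects thus ran the way that slower development of the whole embryo would give. That cause was not tested for either list and stays open. The light-responsive gene cry5 was 1.66-fold higher (0.74 ± 0.1, adjusted p = 7.7e-05; 1 of its 2 other probes also higher), and the melatonin synthesis gene aanat2 stood at -0.09 ± 0.08.

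In all 6911 probes passed at 36 hpf, 3498 higher and 3413 lower, with 2933 gene symbols. The median change was 1.23-fold, and 142 probes differed at least 2-fold, 31 higher and 111 lower. The balance depends on scaling: with 75th percentile scaling 5119 were higher and 2312 lower, 68.9% higher against 50.6%. Without normalization between arrays 1798 passed, 413 higher and 1385 lower (23% higher), and slc30a1a (0.2, adjusted p = 0.39), urod (0.47, 0.069) and hmbsa (0.29, 0.23) no longer did at 36 hpf.

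**Figure D3:**
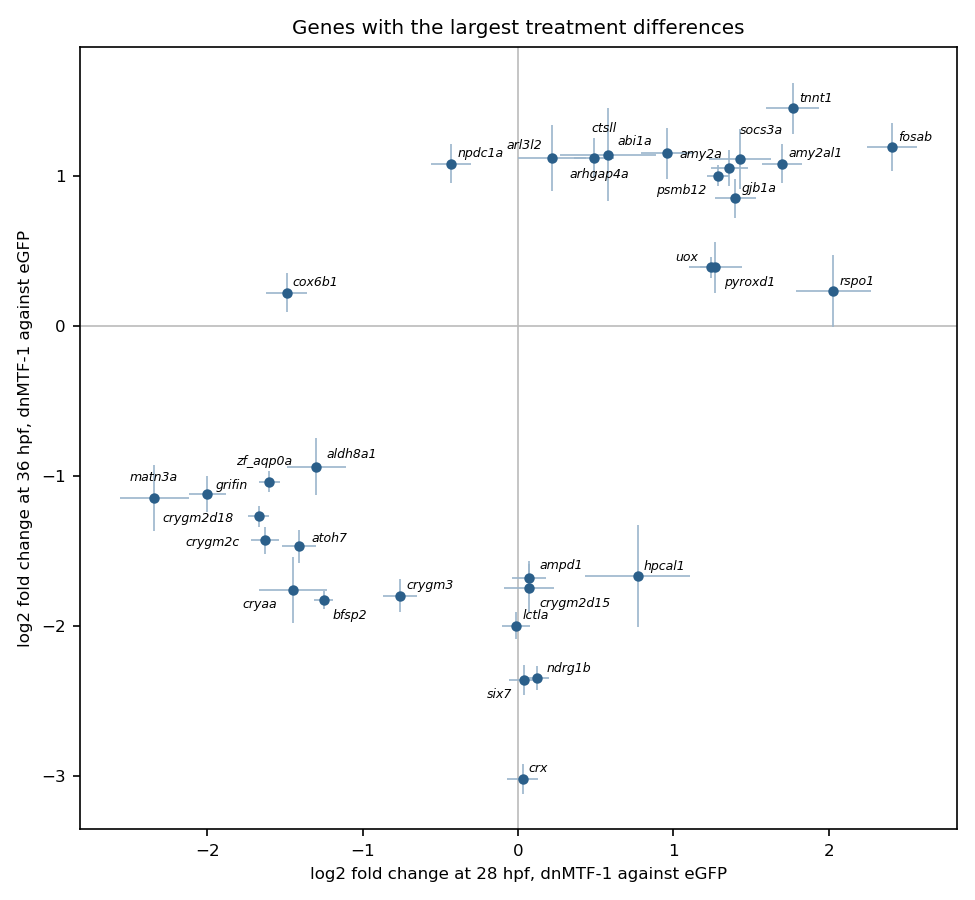
Log2 fold change of dnMTF-1 against eGFP at 28 hpf (x axis) and 36 hpf (y axis) for the genes with the highest rises and deepest falls at either time, with SE bars (4 arrays per group). Most lens genes lie low on the left. Near 0 on the x axis crx, six7, ndrg1b and lctla lie at the bottom, with the lens gene crygm2d15 above them. The genes fosab and tnnt1 lie at the upper right.

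**Figure D4:**
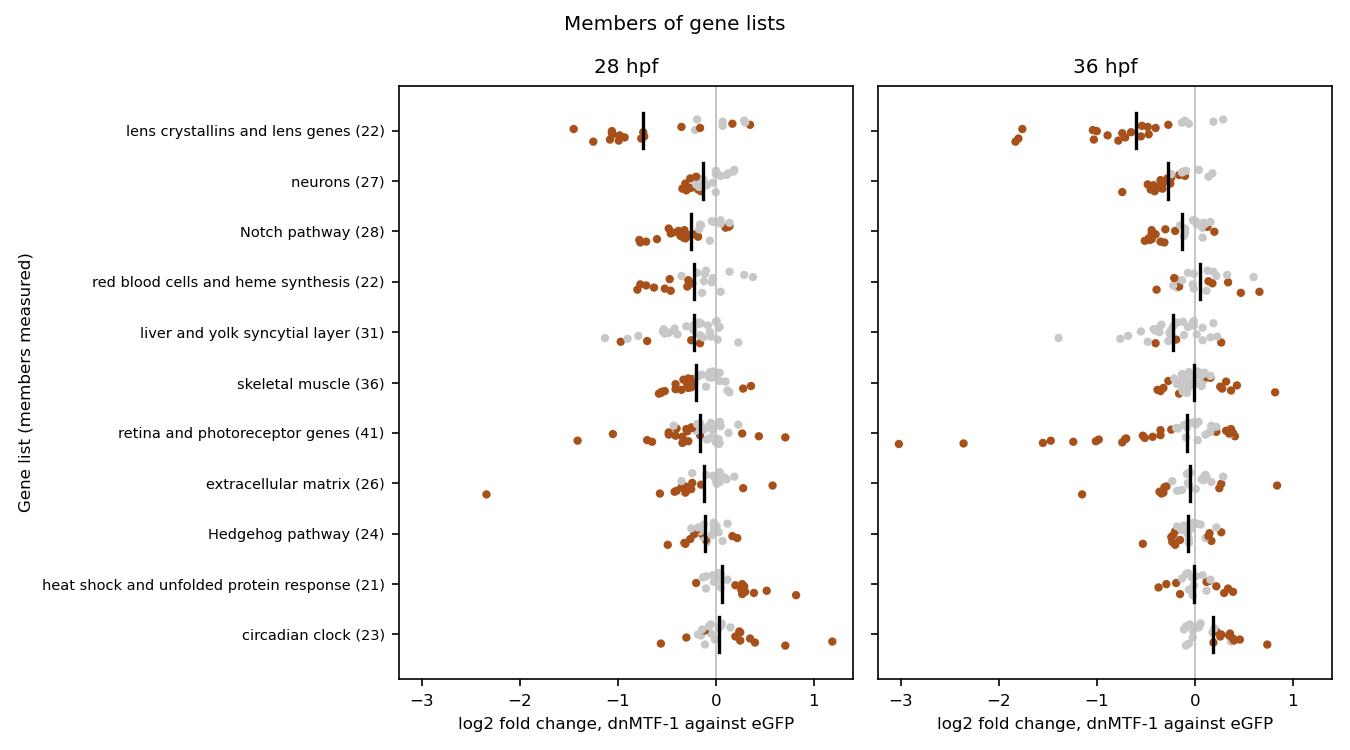
Log2 fold change of the measured members of 11 gene lists that passed the test at 28 or 36 hpf, 1 point per gene, orange where the adjusted p was under 0.05, with a black bar at the median. The lens list has its medians at -0.74 and -0.6.

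Many genes changed the same way at both times, which share no array. The pools of a treatment were divided after injection and may share injection and handling, so this agreement is not a replication. Of the probes higher at 28 hpf, 1310 were also higher at 36 hpf (529 expected if the times were unrelated), 1275 were lower at both (461 expected) and 291 went opposite ways (988 expected). Across 16537 genes, which are not independent replicates, the fold changes at the 2 times correlated at r = 0.37. Over both times together 8338 probes passed, 4280 higher and 4058 lower, and 84 of them differed at least 2-fold. With 75th percentile scaling 5775 were higher and 3225 lower, 64.2% higher against 51.3%.

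The treatment by time interaction asked which effects differed between 28 and 36 hpf. The effect was more negative at 36 hpf on crx (difference -3.05 ± 0.15, adjusted p = 9.2e-09), ndrg1b (-2.47 ± 0.11, adjusted p = 9.2e-09), six7 (-2.4 ± 0.14, adjusted p = 1e-07) and lctla (-1.99 ± 0.12, adjusted p = 1.9e-07). For hpcal1, at background in 3 of the 4 groups, the difference was -0.98 with those groups at the lowest well-above-background level, and its fitted value rests on background. The other way, cox6b1 was lower at 28 hpf and stood at 0.22 at 36 hpf (difference 1.71 ± 0.18, adjusted p = 3.8e-05), and npdc1a went from -0.43 to 1.08 (1.51 ± 0.19, adjusted p = 0.00015). The decapping enzyme gene dcps went from -0.47 to 0.78 (1.25 ± 0.14, adjusted p = 6.5e-05). The steroid synthesis gene cyp11a1.1 went from -1.16 to 0.12 (1.28 ± 0.23, adjusted p = 0.0026, but 0.061 with the deposited values, where the difference was 1). The photoreceptor retinoid carrier gene rbp3 was at background in dnMTF-1 embryos at 28 hpf, at least 1.08-fold lower, and stood at 0.37 at 36 hpf, a difference of 0.48 with that group at the same level.

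Groups differed between the times as well. Skeletal muscle and red blood cell genes, lower at 28 hpf, stood at medians of -0.01 and 0.05 at 36 hpf (differences 0.19, adjusted p = 4.8e-06, and 0.33, adjusted p = 5.8e-06; both 0.5 with an estimated correlation). Neuron genes were lower by more at 36 hpf (-0.15, adjusted p = 0.0018, 0.72 with an estimated correlation). Of 22 red blood cell genes 5 rose and 3 fell at 36 hpf, among the former urod (0.66 ± 0.08) and hmbsa (0.47 ± 0.05), and hsp70 stood at -0.02 ± 0.09. In all 2767 probes passed, 1211 with a more positive and 1556 with a more negative effect at 36 hpf (43.8% positive, 59.5% after 75th percentile scaling), and 752 passed without normalization, 28 more positive and 724 more negative (3.7% positive).

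Between 28 and 36 hpf lens and neuron genes rose and clock genes fell in eGFP embryos. The highest rise was ampd1 (63.3-fold, 5.99 ± 0.11), followed by atoh7 (20.8-fold, 4.38 ± 0.11), crygm3 (4.35), crygm2c (4.2), cryaa (4.03), lctla (3.98), crx (15.6-fold, 3.96 ± 0.1), ndrg1b (3.47), crygm2d18 (3.39) and the red opsin gene opn1lw2 (3.27). Clock genes fell: per1b by 4.04 ± 0.07 (16.4-fold), tefa by 2.62, cry5 by 2.52, nr1d1 by 2.4 and per2 by 1.97. The Nodal antagonist gene lft2 (-2.41), the cathepsin genes ctsh (-2.38) and ctss1 (-2.2), the troponin gene tnnt2c (-2.24) and vent (-2.19) were also lower. At 36 hpf nr1d1 and vent were each well above background on 2 of 4 eGFP arrays, so their falls rest partly on values near background. The adjusted p-values of these genes were 7.8e-15 to 0.0035, the latter for ctss1, whose other probes went 1 up and 1 down and whose mean over probes did not pass (adjusted p = 0.083). Lens genes rose in 17 of 22 cases (median 1.52, adjusted p = 5.1e-11, 0.034 with an estimated correlation) and clock genes fell in 16 of 23 (median -0.44, adjusted p = 4.1e-05, 0.034 with an estimated correlation). Retina and photoreceptor genes rose in 20 of 41 cases and fell in 7 (median 0.25, adjusted p = 6.6e-05, 0.2 with an estimated correlation). Neuron genes rose in 26 of 27 cases (median 0.71, adjusted p = 1.6e-13, 0.17 with an estimated correlation) and cell cycle genes fell in 21 of 30 (median -0.23, adjusted p = 0.00022, 0.56 with an estimated correlation).

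The same interval in dnMTF-1 embryos held smaller rises for crx, ndrg1b and lctla. Between 28 and 36 hpf crx rose by 0.91 (1.87-fold), ndrg1b by 1 and lctla by 1.99, against 3.96, 3.47 and 3.98 in eGFP embryos, while atoh7 changed by 4.32 against 4.38, cryaa by 3.72 against 4.03 and per1b by -4.11 against -4.04. The difference between the treatments did not pass the test for these last 3 (interaction adjusted p = 0.84, 0.54 and 0.68). The red opsin gene opn1lw2 rose by more, 3.91 against 3.27 (interaction adjusted p = 0.041), and the retina list as a whole did not pass the interaction test (median -0.03, adjusted p = 0.28). In eGFP embryos 10229 probes changed with time, 4660 up and 5569 down, and in dnMTF-1 embryos 10386, 4654 up and 5732 down. With 75th percentile scaling 5784 rose and 4542 fell in dnMTF-1 embryos (56% up against 44.8%), and without normalization 5224 probes passed in eGFP embryos, 64.9% of them up, and 7298 in dnMTF-1 embryos, 23.8% up.

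Genes that rose between 28 and 36 hpf in eGFP embryos were on the whole lower in dnMTF-1 embryos. This was counted by sign, not by test, outside the lens and retina lists, with genes chosen on 2 eGFP arrays per time and compared with the other 2, a check added after the data had been seen. Over the 36 ways to divide them, genes that rose at least 2-fold in eGFP embryos were lower in dnMTF-1 embryos in a mean of 70.5% of cases at 28 hpf (range 64.1 to 76.7) and 86.8% at 36 hpf (82.6 to 89.4). For all genes the shares were 47.6% and 48.2%. Genes that fell at least 2-fold were higher in 54.4% (44 to 63.1) and 85% (67.1 to 92.4). Across 16537 genes the slope of the treatment effect on the developmental change was -0.085 at 28 hpf (SD 0.009 over the 4 dnMTF-1 arrays, r = -0.147) and -0.29 at 36 hpf (SD 0.03, r = -0.469), with eGFP arrays split so that no array entered both axes. Genes are not independent replicates, and with 75th percentile scaling the 28 hpf slope was -0.05. The change from 28 to 36 hpf is called developmental here. It may also hold a change in time of day under the light cycle, which these samples cannot separate from age.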

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

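The interaction tests, the search for arrays that stand apart and the splits of the arrays were planned, and the tests that weigh explanations for the last 3 patterns below were chosen after the result was seen.

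Many treatment effects differed between 28 and 36 hpf by the test of the interaction itself, 2767 probes in all and 62 of the named probes. Values here are the log2 effect of dnMTF-1 at 36 hpf minus that at 28 hpf. A negative value can thus be a smaller rise, as for amy2al1, and a positive one a smaller fall, as for grifin. Lens and eye genes with a more negative effect at 36 hpf were crx (-3.05), six7 (-2.4), lctla (-1.99), crygm2d15 (-1.81), crygm3 (-1.04), isl1a (-0.74) and bfsp2 (-0.58), and those with a more positive one were grifin (0.88), opn1lw2 (0.64), zf_aqp0a (0.56) and crygm2d18 (0.4). For metal and stress genes the values were -2.47 for ndrg1b, -1.64 for mt2 probe A_15_P105247, -1.22 for fosab, -0.84 for hsp70, -0.66 for casp8 and -0.41 for sdf2l1. Neural and clock genes stood at -0.8 (aanat2), -0.26 (zc4h2), 0.29 (en2a), 0.36 (ascl1a), 0.46 (ascl1b), 0.5 (per2) and 0.85 (cry5). Muscle and blood genes stood at 0.42 (pvalb1), 0.48 (pvalb4), 0.61 (hmbsa), 0.61 (urod) and 0.68 (tnnt2c). Other genes with a more negative effect at 36 hpf were rspo1 (-1.8), ampd1 (-1.75), pyroxd1 (-0.88), uox (-0.85), amy2al1 (-0.62) and prox1a (-0.24). Members of further lists stood at -1.04 (hamp), -0.78 (krt15), -0.6 (cxcr4b), -0.56 (lef1), -0.54 (tfap2a), -0.53 (gata2a), -0.4 (tbx2b), -0.35 (ccne2), -0.35 (mmp2), -0.33 (dio2), -0.31 (fabp7a), -0.29 (slc39a14) and -0.18 (fli1), or at 0.26 (rpa2), 0.27 (fth1b), 0.49 (wfikkn1), 0.58 (ldha) and 0.58 (mmp9). Other genes with a more positive effect were cox6b1 (1.71), npdc1a (1.51), cyp11a1.1 (1.28), dcps (1.25), ctsh (1.16) and arhgap4a (0.63). For hpcal1, rbp3 and matn3a the fitted differences of -2.44, 1.41 and 1.19 rest on groups with no array above background. With such groups at the lowest well-above-background level they were -0.98, 0.48 and -0.18, so the direction for matn3a is not established. Among gene lists, red blood cells (0.33), skeletal muscle (0.19) and cell cycle (0.08) had higher medians at 36 hpf, and neurons (-0.15) a lower one. None of these 4 passed with an estimated correlation (adjusted p = 0.5, 0.5, 0.72 and 0.72), and the cell cycle list passed at 0.012 without it.

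In 20 of 428 groups of 4 arrays (4.7%, where chance gives about 5%) 1 array stood far from the other 3, and 5 of these were dnMTF-1 replicate 4 at 36 hpf. In that array the log2 signal was 8.78 for aanat2 (others 8.94 to 8.96), 15.11 for ascl1b (14.85 to 14.89), 9.83 for crygm3 (9.43 to 9.48), 9.88 for lctla (9.47 to 9.49) and 10.95 for lef1 (10.61 to 10.65). In dnMTF-1 replicate 1 at 36 hpf it was 9.99 for cry5 (9.43 to 9.51), 8.67 for per1b (8.98 to 9.02), 8.04 for uox (8.18 to 8.2) and 16.37 for krt91 (16.64 to 16.65), and in replicate 2 it was 13.58 for slc30a1a (13.49 to 13.5). Among eGFP arrays at 36 hpf, replicate 4 stood apart for isl1a at 11.99 (11.88 to 11.89) and matn3a at 8.64 (8.88 to 8.93), replicate 2 for gjb1a at 7.62 (7.83 to 7.84) and replicate 1 for pyroxd1 at 9.42 (9 to 9.03). At 28 hpf, eGFP replicate 3 stood apart for en2a at 11.74 (11.58 to 11.6), dnMTF-1 replicate 2 for amy2al1 at 8.8 (9.06 to 9.1) and prdx6 at 13.5 (13.64 to 13.67), and dnMTF-1 replicate 3 for hpcal1 at 3.13 (4.38 to 4.52) and nkx2.7 at 11.85 (11.99 to 12). The SD between duplicate spots was 0.329 in dnMTF-1 replicate 4 at 28 hpf, against 0.243 to 0.253 in the other 3 arrays of that group.

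Other divisions of the same arrays gave far fewer probes, except 1 for the interaction. At 28 hpf the real split of 8 arrays gave 5710 probes and the highest of the others 1, at 36 hpf 6911 and 12, for time in eGFP embryos 10229 and 1, and for time in dnMTF-1 embryos 10386 and 197. In each case 1 of 35 splits, the real one, gave as many, the smallest share that 35 splits allow. This argues against a chance division of the arrays. The real split also divides the slides, so it does not separate group from slide. For treatment over both times the real 8338 was the highest of 100 splits, and the next, 2762, kept the treatment of all 8 arrays at 28 hpf and of 6 of 8 at 36 hpf. For the interaction 2 of 100 splits gave as many as the real 2767. The other, with 3967, kept the treatment of all 8 arrays at 28 hpf and of 2 of 8 at 36 hpf, so it follows the structure of the samples. The number of gene lists past the test, 16, was reached by 8 of 100 splits, with 24 the highest and 9 the median of the others, so chance is not excluded for that number.

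Lens genes, and less so retina genes, were lower in dnMTF-1 embryos at both times. Normalization is argued against as the cause for the lens list, whose weakest median over both times and the scalings tried was -0.56, but stays open for the retina list, whose median was 0.03 at 36 hpf after 75th percentile scaling with members going both ways, although its fall relative to other genes passed camera there too (adjusted p = 0.0003). Slower development of the whole embryo stays open as a cause of the lens fall at 28 hpf. Outside the lens and retina lists the slope of the treatment effect on the developmental change was -0.078 against -0.313 within the lens list. The ratio of 0.25 decides nothing, since a delay at 28 hpf would follow the change before 28 hpf, which no array measured. At 36 hpf that ratio was 0.65 (-0.281 against -0.43), and 0.64 after allowing for what a shared eGFP slide could add, so slower development may account for much of the fall then. An effect of blocked MTF-1 on the eye, and handling that differed between the groups, stay open and were not tested apart from this. Slower development also stays open for the neuron fall and the clock rise at 36 hpf, for which it was not tested.

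Most of the 5710 and 6911 probes past the test differed by little, with medians of 1.21-fold and 1.23-fold, and each group lay on its own slide. Slide differences unrelated between the times are argued against, since the effects at 28 and 36 hpf, which share no slide, correlated at r = 0.38 across genes with trends in GC content and signal taken off. The eGFP slides of both times were scanned before the dnMTF-1 slides, so scanning order follows the treatment at both times. Differences in labelling, hybridization or scanning that follow the treatment were weighed on 8 spike-in probes. Less their common shift (-0.06 and -0.07), their median difference was 0.1 and 0.16 of the median called change at 28 and 36 hpf. With the shift left in it was 0.2 and 0.37. The highest single difference, less the shift, was 0.292 at 36 hpf, beside a median called change of 0.294. The called probes were picked for large differences and the spike-ins were not, so low ratios were favoured in advance. Such differences therefore stay open as a cause. Spike-ins say nothing of embryo rearing, collection or RNA extraction, and a treatment effect cannot be separated from these. The biological reading, a wide and shallow response to dnMTF-1, may hold but was tested on the same arrays.

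The 3 metallothionein probes disagreed, with 1 falling 6.96-fold at 36 hpf and the others not falling. Signal near background is argued against for the probe that fell, A_15_P105247, since it was well above background on 16 of 16 arrays. Its sequence shares runs of at most 8 and 10 of 60 bases with the other 2 probes, which does not settle whether they read the same transcripts. That the probes read different metallothionein genes, of which 1 may depend on MTF-1 more than the others, stays open.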

How the results depend on the processing

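All alternatives here were planned except the slope without the lens and retina lists, which was chosen after the data had been seen and gave -0.078 against -0.085. Outside the leave-one-out runs, counts of probes or lists stayed within 1.5 times the reported one, and slopes within the spread between arrays, in 96 cases and moved further in 25. Named genes kept direction and side of the threshold in 2485 cases, lost a call in 59 (38 without normalization), gained 1 in 19, moved in 13 and turned round in 6, and gene lists kept it in 444, gained it in 17 and lost it in 19. Without normalization between arrays the counts were 2230 at 28 hpf, 1798 at 36 hpf, 3029 for treatment over both times, 752 for the interaction and 5224 for time in eGFP embryos, and the cause was not tested. The 28 hpf slope was -0.05 with 75th percentile scaling and -0.055 where the eGFP arrays entered both axes, which share noise by construction. Stricter rules gave fewer probes by construction. At adjusted p under 0.01 they left 3139, 4105 and 1071 (28 hpf, 36 hpf, interaction), and at 2-fold or more 111, 142, 84 (both times), 171 (interaction), 783 and 679 (time in eGFP and dnMTF-1 embryos). The methods' 2-factor test was run as a linear model without permutations. At Benjamini-Hochberg adjusted p under 0.01 it gave 2909, 3844, 5276 and 929 (28 hpf, 36 hpf, both times, interaction). The limma test gave 3139, 4105, 5599 and 1071 at that threshold. At unadjusted p under 0.01 the 2-factor test gave 4940, 5837, 6983 and 2998. The methods' rank product gave 868 at 28 hpf and 953 at 36 hpf, or 644 and 704 over probes past the 2-factor test. The cause of the rank product's lower counts, and of what difference from limma remained, was not tested. With an estimated correlation 0 lists passed camera, against 16, and fry called 24. Leaving out each array gave 4419 to 5182 probes at 28 hpf, 5801 to 6879 at 36 hpf, 7617 to 8459 over both times, 2122 to 2950 for the interaction, 9438 to 9796 and 9562 to 10200 for time in eGFP and dnMTF-1 embryos, and 14 to 18 lists. For the 28 hpf slope only the dnMTF-1 arrays of that time were left out in turn, which gave -0.089 to -0.083. The eGFP arrays were not left out there. With the replicate number as a block the counts were 5464, 6683, 8076, 2477, 10114 and 10330, with 16 lists, and mc1r at 36 hpf lost its call (adjusted p = 0.053). The sign turned round for mt2 probe A_15_P113136 at 36 hpf without normalization (-0.02, cause not tested), and, where the probes of a name were averaged, for it and A_15_P115043 (-0.33 at 28 hpf and -0.81 at 36 hpf, from the probe that fell) and for tfap2a at 28 hpf (-0.08 against 0.19). A slide block could not be run, since slide and group coincide. All arrays were scanned on 1 day, the eGFP slides before the dnMTF-1 slides, so scanning order follows the treatment. No spot was saturated. Signal over background limits dim genes such as matn3a, hpcal1 and rbp3 to lower limits.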

Other observations

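Single members of other gene groups differed clearly where the group as a whole did not pass. Epidermal keratin krt91 was lower in dnMTF-1 embryos at 28 hpf (-1.19 ± 0.07, adjusted p = 1.4e-08) and 36 hpf (-1.09 ± 0.07, adjusted p = 2.8e-08) and krt15 at 36 hpf (-0.87 ± 0.07), while of 32 genes of epidermis, hatching gland and ionocytes 6 rose and 4 fell at 28 hpf and 6 rose and 3 fell at 36 hpf (medians -0.01 and -0.04, adjusted p = 1 and 0.79). The lysozyme gene lyz, which the interferon list also holds, fell at both times (-0.85 ± 0.15 and -0.57 ± 0.15) and the chemokine receptor gene cxcr4b at 36 hpf (-0.69 ± 0.04), and of 21 macrophage and neutrophil genes 6 fell and 0 rose at each time (medians -0.14 and -0.11, adjusted p = 0.05 and 0.062, both 0.88 with an estimated correlation). Over the other alternatives its adjusted p was 0.036 to 0.11 at 28 hpf and 0.038 to 0.081 at 36 hpf. It passed at 28 hpf without eGFP replicate 1 (0.019) or 2 (0.02) or dnMTF-1 replicate 1 (0.0093) or 4 (0.031) of that time, or without eGFP replicate 1 (0.047) or 4 (0.046) or dnMTF-1 replicate 3 (0.046) or 4 (0.045) of 36 hpf. It passed at 36 hpf without eGFP replicate 3 (0.034) or 4 (0.028) or dnMTF-1 replicate 3 (0.019) of that time. Interferon and innate immune genes rose in 9 of 22 cases and fell in 4 at 28 hpf, and 5 and 2 at 36 hpf (medians 0.2 and 0.09, adjusted p = 0.062 and 0.42), with irf1b at 0.93 ± 0.12 and 0.47 ± 0.12 and the iron hormone gene hamp at 0.21 ± 0.12 and -0.83 ± 0.12. The interferon list passed at 28 hpf with 75th percentile scaling (0.019), the deposited values (0.036), fry (0.00025) and without 28 hpf eGFP replicate 4 (0.036). The antioxidant regulator sqstm1 rose at both times (0.51 ± 0.04 and 0.54 ± 0.04), as did prdx6 (0.25 ± 0.04 and 0.22 ± 0.04), while of 20 NRF2 and glutathione genes 5 rose and 3 fell, then 5 and 2 (medians 0 and 0, adjusted p = 0.84 and 0.58). In the Wnt list lef1 fell at 36 hpf (-0.69 ± 0.06) and sp5l rose at both times (0.63 ± 0.06 and 0.61 ± 0.06), and 3 genes rose and 9 fell of 30, then 7 and 6 (medians -0.03 and -0.04, adjusted p = 0.27 and 0.89). The gelatinase genes stood at 0.55 ± 0.05 and 0.2 ± 0.05 for mmp2 and at -0.14 ± 0.08 and 0.44 ± 0.08 for mmp9, with 4 and then 3 of 11 metalloproteinase genes higher and 0 lower (medians 0.09 and 0.07, adjusted p = 0.3 and 0.43).

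For the remaining lists the values at 28 and then 36 hpf were as follows. Neural progenitor and glia genes rose in 7 and fell in 10 of 31 cases, then 5 and 12 (medians -0.08 and 0, adjusted p = 0.3 and 0.3), with the myelin gene mpz at -0.57 ± 0.05 and -0.41 ± 0.05 and fabp7a at -0.17 ± 0.05 and -0.48 ± 0.05. Neural crest and pigment genes rose in 6 and fell in 3 of 22 cases, then 2 and 5 (medians 0.01 and 0.05, the latter with a mean of -0.02 and a downward test, adjusted p = 0.89 and 0.92). The pigment cell receptor gene mc1r stood at -0.53 ± 0.08 and -0.23 ± 0.08 and tfap2a at 0.19 ± 0.05 and -0.35 ± 0.05. The call for mc1r at 36 hpf ended without eGFP replicate 1 (adjusted p = 0.074), 2 (0.055) or 3 (0.067) or dnMTF-1 replicate 2 (0.081) or 4 (0.095), and with 75th percentile scaling (-0.06, adjusted p = 0.6). That for tfap2a at 28 hpf ended without dnMTF-1 replicate 3 (0.054) and with 75th percentile scaling (0.14, adjusted p = 0.1). Of 30 cell cycle genes 4 rose and 4 fell, then 9 and 3 (medians -0.08 and 0.05, adjusted p = 0.3 and 0.22, and 0.0017 at 28 hpf with 75th percentile scaling), with ccne2 at 0.4 ± 0.06 and 0.05 ± 0.06. Of 25 blood vessel genes 4 rose and 3 fell, then 7 and 7 (medians 0 and 0, adjusted p = 0.89 and 0.68), with gata2a at 0.01 ± 0.05 and -0.52 ± 0.05. Of 22 heart genes 1 rose and 1 fell, then 1 and 2 (medians -0.09 and -0.08, adjusted p = 0.43 and 0.43), with nkx2.7 at 0.28 ± 0.06 and 0.36 ± 0.06.

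Hypoxia and aryl hydrocarbon response genes rose in 5 and fell in 5 of 16 cases, then 6 and 3 (medians 0.06 and 0.08, adjusted p = 0.93 and 0.42), with ldha at -0.61 ± 0.07 and -0.03 ± 0.07. Of 13 iron and copper genes 3 rose and 3 fell, then 4 and 2 (medians -0.03 and 0.04, the former with a mean of 0.01, adjusted p = 0.93 and 0.58), with cox17 at 0.29 ± 0.05 and 0.42 ± 0.05 and fth1b at -0.33 ± 0.04 and -0.07 ± 0.04. Of 23 selenoprotein genes 4 rose and 4 fell, then 4 and 3 (medians 0.09 and -0.01, adjusted p = 0.43 and 0.93), with the thyroid hormone deiodinase gene dio2 at -0.41 ± 0.07 and -0.74 ± 0.07 and selenot1a at 0.4 ± 0.06 and 0.26 ± 0.06. Of 27 pancreas and gut genes 3 rose and 4 fell, then 2 and 6 (medians -0.03 and -0.03, adjusted p = 0.88 and 0.43), and of 14 notochord and floor plate genes 1 rose and 3 fell, then 3 and 3 (medians 0 and 0.09, adjusted p = 0.67 and 0.78), with epyc at -0.41 ± 0.07 and -0.31 ± 0.07 (-0.13, adjusted p = 0.28, at 28 hpf as the mean of its probes). Clock genes at 28 hpf rose in 8 and fell in 3 cases (median 0.03, adjusted p = 0.58), with aanat2 at 0.71 ± 0.08. At 36 hpf lists called at 28 hpf alone stood at medians of -0.05 for extracellular matrix (adjusted p = 0.52), -0.01 for heat shock (0.84), -0.07 for Hedgehog (0.3), -0.22 for liver (0.3), 0.05 for red blood cells (0.52) and -0.01 for skeletal muscle (1). With fry, which makes no comparison with other genes, the clock (adjusted p = 0.04) and metalloproteinase (0.028) lists passed at 28 hpf, and at 36 hpf the hypoxia (0.031), blood vessel (0.039), Hedgehog (0.048), interferon (0.034) and pancreas and gut lists (9.6e-05) did. Counts here are over all probes tested.

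The rise of fosab raised the hypothesis of a wider rise of immediate-early genes, tested after the result was seen on 33 other such genes, of which 21 were measured. At 28 hpf 9 rose and 2 fell, with a median log2 fold change of 0.1, and at 36 hpf 7 rose and 7 fell. Since the members went both ways, the median decides nothing, and the hypothesis stays open.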
